A study of Mus musculus with 35 samples.

How the data were processed

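The samples were plantaris muscles of wild-type mice, either unperturbed (basal) or collected after denervation, which makes the muscle shrink, or after overload, which makes it grow. Single nuclei were profiled from 19 libraries (basal, and 3 or 7 days after either surgery), sorted single cells from 10 libraries (5 of gene expression and 5 of the tags that mark the condition of a cell), and tissue sections by Visium from 6 libraries (sham, denervation and overload at 7 days). Per the labels, a nucleus suspension held 2 pooled plantaris muscles, and the sorted cells came from 10 to 16 pooled muscles per condition. The library names give libraries of the same suspension run on 2 chips, and these were summed, which left 13 suspensions in 2 experiments, Exp1 and Exp2. Nothing in the labels says that suspensions of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical. The numbers of the suspensions did not pair them across conditions.

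The deposited nucleus and cell matrices held counts of unique molecular identifiers (UMIs) per gene for barcodes that the authors had called as cells, with no normalization. The deposited tag matrices held UMI counts of each multiplexing oligo per cell, and the deposited Visium matrices held UMI counts per gene and spot under tissue. Deposited beside the Visium matrices were a table of the other kind, which marks with 1 each spot over tissue, and a score per gene, Moran's I, which the authors' software computes as the spatial autocorrelation over spots. Per the submitters' processing notes, Cell Ranger 7.1.0, Space Ranger 2.0.0, Trim Galore 0.6.10 and Salmon 1.10.3 were used, with the builds GRCm39, mm10 and GRCh38 named without a role. Because the build behind a gene is then not certain, genes are given by symbol and Ensembl identifier and no coordinates are printed.

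Nuclei with at least 500 UMIs, at least 300 genes and at most 5.0% mitochondrial UMIs were kept, and doublets were scored with scrublet (expected rate 0.06) in scanpy 1.11.5 and left out above a score of 0.25. A fixed limit was used because the threshold that scrublet sets itself differed between libraries. Of 83084 barcodes, 77849 passed the limits and 76269 remained after 1580 doublet calls. Counts were scaled and log transformed, 3000 variable genes and 30 principal components were taken, and Leiden clusters (15 neighbours, resolution 1.5; igraph 0.11.9) were named from marker lists. A cluster of nuclei took the name of a class when at least 3 of its markers were detected. Their mean log2 fold had to be at least 2, except for body myonuclei, which had no limit on the fold. A cluster stayed unnamed when over 10% of its nuclei were doublet calls or when a second class scored 80% of the first. Of 40 clusters 35 were named, and 3492 nuclei stayed unnamed. Class names stand for marker expression, so nuclei are described as resembling a class. Body myonuclei are the nuclei along a muscle fibre outside its nerve and tendon contacts. The junction and differentiating myoblast classes were named by genes that themselves change with denervation or overload. Sorted cells were kept at 1000 UMIs, 500 genes and at most 15.0% mitochondrial UMIs, with a doublet score limit of 0.2 and resolution 1.0. The fold limit of 2 did not hold for their clusters. Muscle stem cell clusters among them were named at mean log2 folds from 0.47 to 2.20. A tag was assigned to a cell when it held at least 80% of the tag UMIs and at least 10 UMIs. Visium spots with at least 500 UMIs were summed per section.

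Counts were summed per class and suspension, with at least 20 nuclei (10 for junction myonuclei), and tested with edgeR 4.0.16 on R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood F test with robust spread and experiment as a term. All groups share an estimate of the spread, and the single suspension of 7-day denervation is assumed to vary like the others. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 are called changed, and rose and fell are written of such genes. For classes other than body myonuclei the denervation and overload effects are means over the days present. In mural, Schwann and junction nuclei overload is 7 days alone, as each 3-day overload suspension held too few of them. In tenocytes 3-day overload is replicate 1 alone, with 24 nuclei, and it weighs as much as 7 days. Class shares were tested in edgeR on nucleus counts with the total as offset. Visium sections were tested with edgeR in the same way, without a term for experiment. CPM are counts scaled to the total over the genes tested in each sum, adjusted by its TMM factor. They therefore depend on which sums are scaled together. CPM are given as means over suspensions with the SD. Where a group had 0 counts, the fold is a lower limit set by 3 counts over the group. Where it had 1 to 3 counts, the ratio of CPM is given with its exact counting interval. Intervals and limits cover counting error only.

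Before the data were examined, the tests, the alternatives, the marker lists, 26 gene lists and a rule for the genes named were fixed. For each comparison of body myonuclei with basal the rule takes the 8 genes with the largest log2 fold change in each direction, among those called, with an average log2 CPM of at least 3 and on the fitted side of the basal suspension of the same experiment in every treated suspension. It takes 5 in each direction where denervation and overload are compared directly, 4 for each other class and 8 for Visium. Predicted genes, mitochondrial and ribosomal protein genes and sex-linked genes were passed over. Members of the lists may also be named. The glycolysis list holds 16 symbols, and in body myonuclei 17 genes, as Aldoa was tested under 2 identifiers. Some genes that the rule or the lists name are not reported here. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Each list was fixed from general knowledge of muscle, and the count adjusted over the list alone is given where it differs from the count over all genes. Lists overlap: Ncam1 and Tnc stand in more than 1, and markers of other cells include collagens of the matrix list. No list called by camera at the preset correlation was called with an estimated one. In nuclei, lists whose median, mean and camera direction differed in sign were all among those not called. For 4 lists that camera called, all in comparisons with 3-day overload, fry gave the opposite direction and called none of them.

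Alternatives were DESeq2 1.42.0, no filter on low counts, every library as its own replicate with experiment and chip as the replicate block, no experiment term, each experiment alone, numbered suspensions summed, stricter nucleus limits, doublets kept, other scaling of class shares, and leaving out each suspension or section in turn. After seeing the data, further settings were added: junction myonuclei counted with body myonuclei, the chip 1 library of the Exp2 basal suspension left out, the 2 shallow 3-day overload suspensions of Exp2 left out, genes at least 10 times higher in body myonuclei left out, and the fibroblast class without 2 clusters of mostly overload nuclei. The fixed doublet limits and the limits for sorted cells were also chosen after seeing the data. Each experiment alone held a single basal suspension. The spread in such a fit comes only from the groups with numbered suspensions, so its counts are not a replication of a comparison. Under DESeq2 the median of all genes moved against TMM by -0.30 log2 in body myonuclei for 7-day denervation, -0.12 for 7-day overload and -0.18 between them. It moved by -0.15 and -0.13 in fibro-adipogenic progenitors, -0.10 and -0.12 in muscle stem cells, and -0.12 and -0.11 in macrophages, for denervation and overload.

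The test was also tried on simulated data with 200 genes changed by 1.5-, 2- or 4-fold. For 3-day denervation in body myonuclei 61.2% of the genes changed 2-fold and 92.4% of those changed 4-fold were found, against 11.9% and 34.8% for 3-day overload, whose suspensions are shallow. Of the calls, 18.0% and 3.03% were false. In body myonuclei 13.1% were false for 7-day denervation and 14% for 7-day overload. For denervation it was 6.06% in Schwann cells and 8.7% in Visium. All of these but the 3.03% are above the share that the limit on the adjusted p is meant to allow. The simulated data held only 200 changed genes, far fewer than were called in body myonuclei, so these shares need not carry over. Suspensions held 24011351 to 37778308 UMIs, except 12545517 to 35403222 for 7-day overload and 181373 to 5355073 for 3-day overload. No 2 libraries held identical counts, and pairs of libraries of a group differed by more than sampling noise, with chi-square over its degrees of freedom from 1.13 to 22.3. Libraries of the same suspension on 2 chips gave 2.12 to 7.47. Separate suspensions of Exp1 gave 1.55 for 3-day denervation and 1.8 for 7-day overload, below that range. Those of 7-day overload in Exp2 gave 1.88 to 3.88, and the highest value was between experiments. The tags of the sorted cells could not be paired with conditions from the labels, so those cells enter no comparison, and the planned tag limit of 60% was not tried. Other tools were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and Python 3.11.15.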

Results

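The nucleus data asked how each kind of nucleus in the plantaris responds when the muscle loses its nerve or carries extra load. After filtering, 76269 nuclei remained: 25485 from 2 basal suspensions, 19539 from 3 suspensions of 3-day denervation, 5052 from 1 suspension of 7-day denervation, 3379 from 3 suspensions of 3-day overload and 22814 from 4 suspensions of 7-day overload. Body myonuclei made up 39777 of them. The median depth of a library ran from 769 to 3787 UMIs per nucleus. The 3-day overload suspensions stood apart in depth and quality. Their totals were 181373 to 5355073 UMIs, and the limit on mitochondrial UMIs removed 24.3% of the nuclei of the Exp1 library and 56.8% to 67.2% in the Exp2 libraries. The chip 1 library of the Exp2 basal suspension was also shallow, with a median of 1098 UMIs per nucleus against 3641 on chip 2. It gave 14357 of the 17729 nuclei of basal replicate 2. In that replicate 8.65% of nuclei stayed unnamed. The Visium sections held 1030 to 1311 spots over tissue and 15844676 to 29114108 UMIs each. Their mitochondrial UMIs were 31.1% and 31.5% in denervated, 40.5% and 42.4% in sham and 25.2% and 26.3% in overloaded sections.

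With overload, nuclei resembling macrophages, muscle stem cells, fibro-adipogenic progenitors (the connective tissue cells of muscle) and differentiating myoblasts took a larger share of all nuclei. At 3 days macrophages were 33.7% ± 0.649 (SD, n = 3) of nuclei against 3.48% and 1.48% in the basal suspensions, a log2 change of 3.90 (edgeR adjusted p = 1.23e-08). Differentiating myoblasts reached 5.04% ± 1.84 (log2 change 6.72, adjusted p = 2.39e-13). Body myonuclei were 19.1% ± 11.9 against 51.5% and 72.6% (log2 change -1.65, adjusted p = 0.00247), and 11 classes changed in all. At 7 days of overload 4 classes rose: differentiating myoblasts (1.80% ± 0.255, n = 4, log2 change 5.31, adjusted p = 1.66e-10), macrophages (12.3% ± 2.82, 2.36), muscle stem cells (6.91% ± 1.23, 1.53) and fibro-adipogenic progenitors (26.1% ± 11.95, 1.36). In the single suspension of 7-day denervation, macrophages were 9.56% (log2 change 2.20), Schwann cells 1.33% (2.24), perineurial cells, which sheathe nerves, 1.60% (1.98) and differentiating myoblasts 0.238% (2.45), and these were the 4 classes called. At 3 days of denervation edgeR called 0 classes, with 3 at an unadjusted p under 0.05 (fibro-adipogenic progenitors, macrophages and tenocytes) and 3 called with libraries as replicates in blocks. Several of these calls were lost without 1 suspension or with another scaling. Leaving out the 2 shallow 3-day overload suspensions left 5 classes called at that time, 4 of them among the 11. Body myonuclei (-0.61), fibro-adipogenic progenitors (0.61, from 1.62) and muscle stem cells (0.60, from 1.80) were then not called, each with an adjusted p of 0.35. Without basal replicate 2 the progenitors were at 0.82 (0.2) and the stem cells at 1.13 (0.0933) at 3 days. For 7-day denervation 0 classes were called without 7-day overload replicate 2, without basal replicate 2, with no experiment term or with TMM-style factors, and 2 without 7-day overload replicate 4 or without 3-day denervation replicate 1. Without 7-day overload replicate 2 the 4 changes hardly moved and lost their call narrowly: macrophages 2.18 (adjusted p = 0.0532), Schwann cells 2.23 (0.0532), perineurial cells 1.96 (0.0621) and differentiating myoblasts 2.43 (0.0621). Without basal replicate 2 they were 1.66, 1.49, 1.33 and 1.47. With no experiment term they were 1.95, 1.82, 1.60 and 2.39, and with TMM-style factors 1.75, 1.65, 1.415 and 2.19. For 7-day overload 2 were called without 7-day overload replicate 2 or without basal replicate 2. The rise of fibro-adipogenic progenitors was then 1.23 (adjusted p = 0.126) and 0.69 (0.303), and 1.24 (0.0834) without 7-day overload replicate 1. That of muscle stem cells was 1.54 (0.0517) without 7-day overload replicate 2 and 0.96 (0.222) without basal replicate 2. For 3-day denervation 3 were called without 3-day overload replicate 1, 2 without basal replicate 1, and 1 without basal replicate 2 or without 3-day denervation replicate 3. The rises of differentiating myoblasts and macrophages under overload were called at both times in each of these settings.

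**Figure D1:**
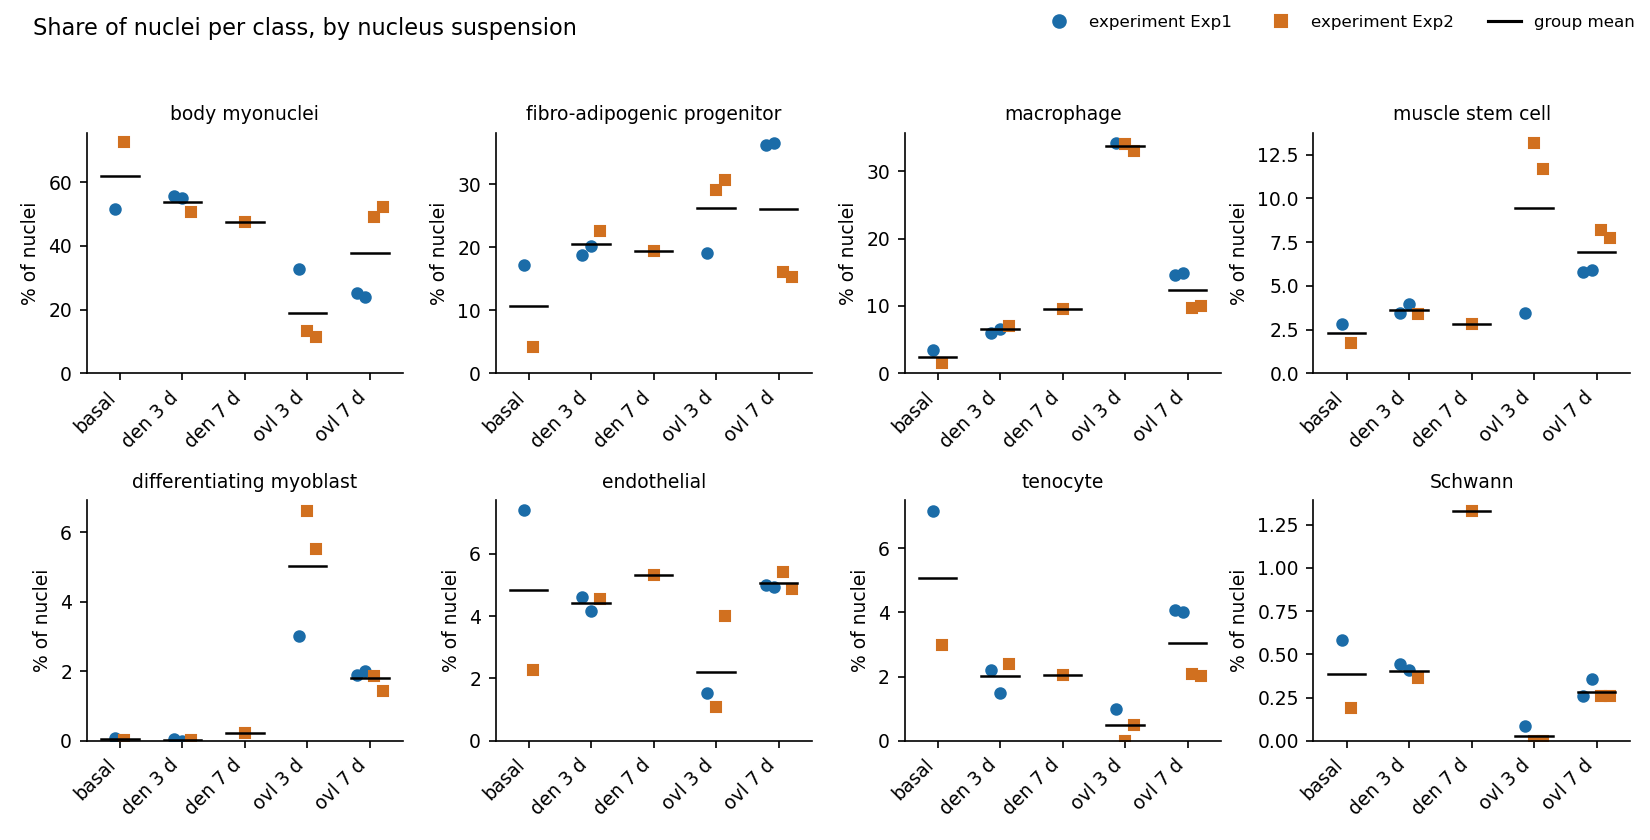
Share of all nuclei (percent, vertical axis) taken by 8 classes in each suspension, by condition; circles are Exp1, squares Exp2 and the line is the mean of the group. Macrophages average 33.7% at 3 days of overload and 12.3% at 7 days, against 3.48% and 1.48% in the basal suspensions.

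Within 3 days of denervation body myonuclei turned on genes of immature and denervated fibres and lost transcripts of fast contraction and energy use. Runx1 (ENSMUSG00000022952), a transcription factor, reached 1683 ± 127 CPM (SD, n = 3) against 6.41 to 8.66 in the basal suspensions, a log2 fold change of 7.79 (SE 0.28). Also among the largest rises were Ankrd1 (9.03), a stretch-responsive protein of the sarcomere, Myh3 (8.06), the embryonic myosin heavy chain, Igfn1 (7.52), and Chrnd (6.90), the delta subunit of the acetylcholine receptor. Mybpc2 (ENSMUSG00000038670), the fast myosin-binding protein C, fell from 551 to 687 CPM to 13.7 ± 5.55 (log2 fold change -5.51). Aqp4, the water channel of fast fibres (-7.01), and Perm1, a regulator of mitochondrial genes (-6.03), fell too. In all, 8919 of 18419 genes changed, 4069 up and 4850 down.

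Of the denervation response genes 15 rose and 2 fell of 18 tested, with Myog, a myogenic transcription factor, at 5.71, Gadd45a at 5.33 and Kcnn3, a potassium channel, at 6.85, while Dach2 and Smox fell (-3.09 and -3.02; camera adjusted p = 5.26e-13). Of 16 synaptic genes 10 rose and 3 fell, or 12 and 3 adjusted over the list alone (adjusted p = 0.0155): Chrng, the fetal receptor subunit, rose by 6.26, Ncam1 by 5.78 and Musk, the receptor kinase that organises the synapse, by 3.26, whereas Chrne, the adult subunit, was at -3.19 and Ache, acetylcholinesterase, at -3.32. The adjusted p of these lists with an estimated correlation were 0.387 and 0.727. Proteasome genes rose together, 25 of 31 with 0 falling (Psmd14 1.45, Psma5 1.09; adjusted p = 2.48e-04), as did 16 of 24 genes of ribosome biogenesis, 17 adjusted over the list alone (Myc 2.01, Gnl3 1.42; adjusted p = 0.00456). With an estimated correlation these adjusted p were 0.684 and 0.667. Of 16 ubiquitin ligases and FoxO targets 6 rose, 7 adjusted over the list alone, and 3 fell, and camera did not call the list (adjusted p = 0.235). Fbxo32 (1.64) and Trim63 (1.42), the ligases known from atrophy, were among those that rose, and Asb2 fell (-0.92).

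Every fast contractile gene tested fell, 13 of 13 (Myh4, the fastest myosin, -3.22), as did 15 of 17 glycolysis genes (Eno3 -4.05, Ldha -2.83), 24 of 25 genes of mitochondrial respiration, 25 adjusted over the list alone (Idh2 -2.99, Cox7a1 -2.57), and 14 of 15 genes of fatty acid use, 15 adjusted over the list alone (Lpl -3.57, Cpt1b -3.25). The camera adjusted p were 1.12e-12, 9.07e-10, 2.91e-10 and 2.91e-10, and with an estimated correlation 0.387, 0.468, 0.48 and 0.48. Angiogenic genes fell in 8 of 14 (Vegfa -3.33; adjusted p = 0.0177, or adjusted p = 0.783 with an estimated correlation). Markers of fibroblasts fell in 8 of 10 (adjusted p = 0.0393, or adjusted p = 0.824 with an estimated correlation), and those of endothelial cells fell in 9 of 10 with 0 rising (1 adjusted over the list alone), a list not called by camera (adjusted p = 0.0873). With libraries as replicates in blocks of experiment and chip 8798 genes changed in this comparison. Each experiment alone held a single basal suspension, so neither replicates the comparison.

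The lists that follow were not called by camera at 3 days of denervation either. Rising and falling members numbered 7 and 5 of 21 for mechanical stress, 3 and 3 of 10 for slow contractile genes (3 and 4 adjusted over the list alone; Tnnt1 1.70, Myl3 -3.61), 4 and 5 of 14 for autophagy (Map1lc3a 1.66), and 7 and 6 of 19 for muscle growth factors (Il15 -3.03, and Mstn, the growth inhibitor myostatin, -1.31). For matrix they were 3 and 10 of 27, for Schwann repair 4 and 3 of 12 (4 and 4 adjusted over the list alone), for myelin 2 and 4 of 10, for quiescent muscle stem cells 0 and 6 of 13, and for activated ones 7 and 3 of 13. Proliferation had 8 and 1 of 18, resident macrophages 1 and 2 of 8, recruited macrophages 3 and 3 of 12, immediate early genes 3 and 6 of 15, and immune markers 2 and 3 of 10.

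After 7 days of denervation, in a single suspension, 9656 genes differed from basal, 4140 up and 5516 down, or 2612 up and 5839 down with DESeq2. Igfn1, a sarcomeric protein, was at 1282 CPM against 0.488 to 1.47 in the basal suspensions (log2 fold change 10.45, SE 0.55), Chrnd at 7.87 and Runx1 at 7.86. Ankrd55 and Atp13a4 had 3 basal counts each, and their CPM ratios were 707 (interval 241 to 3430) and 769 (262 to 3740). Lynx1, a modulator of acetylcholine receptors, fell by 6.92, Mybpc2 by 6.13 and Kcna7, a potassium channel, by 6.30 on the log2 scale. Denervation response genes rose in 15 of 18 and fell in 2 (Gadd45a 5.95; adjusted p = 4.54e-10), and synaptic genes rose in 9 of 16 and fell in 4 (Chrng 7.13, Ncam1 6.60; adjusted p = 0.00696). Their adjusted p with an estimated correlation were 0.417 and 0.725. Falls were counted in 12 of 13 fast contractile, 15 of 17 glycolytic (Gapdh -4.67), 24 of 25 respiratory (Cox7a1 -5.08) and 13 of 15 fatty acid genes (14 adjusted over the list alone). Their adjusted p were 3.63e-12, 1.44e-08, 7.24e-08 and 2.44e-06, and with an estimated correlation 0.387, 0.48, 0.643 and 0.711. Mechanical stress genes rose in 6 of 21 and fell in 3 (adjusted p = 0.0396, or adjusted p = 0.866 with an estimated correlation). Proteasome genes went both ways: 12 rose and 10 fell of 31 with TMM scaling, and 7 rose and 14 fell with DESeq2, with Psmd14 at 1.81 and Psmb6 at -1.55. Among growth factors 6 rose, with follistatin (Fst) at 3.16 and Igfbp5 at 2.71, and 6 fell, with Mstn at -2.54. The suspension was in Exp2, and its spread is assumed, not measured.

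Overload at 3 days raised genes of mechanical stress in body myonuclei. Ankrd1 reached 263 ± 171 CPM (n = 3) against 0.847 to 1.89 in basal (log2 fold change 8.06, SE 0.40), and Dclk1 (ENSMUSG00000027797), a kinase bound to microtubules, 453 ± 20.7 against 2.01 to 2.36 (7.61, SE 0.28). Atf3, a stress-induced transcription factor, was at 662 ± 682 CPM (8.05, SE 1.24), Card14 at 8.65, Rrad at 7.69 and Glis3 at 7.31. Mettl21e, a muscle methyltransferase, had 0 counts and was at least 34.0-fold lower, and Pln, the inhibitor of the calcium pump in slow fibres, at least 24.0-fold lower. Of 21 genes of mechanical stress 13 rose, 14 adjusted over the list alone, and 2 fell (Csrp3 2.17, Enah 3.09; adjusted p = 1.36e-07). Of 18 denervation response genes 14 rose and 2 fell (Myog 4.36; adjusted p = 4.45e-06), and with an estimated correlation the adjusted p of these lists were 0.684 and 0.48. Matrix genes rose in 17 of 27, 19 adjusted over the list alone, with 0 falling (Timp1 5.69; adjusted p = 1.31e-12, or adjusted p = 0.418 with an estimated correlation).

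Fast contractile genes fell in 13 of 13 (Myh4 -3.82), glycolysis genes in 14 of 17 (15 adjusted over the list alone), respiratory genes in 24 of 25 and fatty acid genes in 11 of 15 (13 adjusted over the list alone). The adjusted p were 5.2e-05, 0.0043, 7.75e-04 and 0.00809, and with an estimated correlation 0.643, 0.78, 0.78 and 0.824. Lists of other cells and states rose in the same nuclei: proliferation in 15 of 18, recruited macrophages in 9 of 12 (Lgals3 5.22; 11 adjusted over the list alone), activated muscle stem cells in 9 of 13, immediate early genes in 11 of 15 with 2 falling, and immune markers in 8 of 10 (Ptprc 4.85). Their adjusted p were 3.84e-04, 0.00189, 7.55e-04, 3.84e-04 and 0.0153, and with an estimated correlation 0.727, 0.78, 0.643, 0.468 and 0.798. The immune markers in body myonuclei stood at 7.3%, 0.928% and 8.6% of their level in macrophages of the same suspension, against 0.527% and 0.702% in basal. Proteasome genes rose in 9 of 31 and fell in 3, and ribosome biogenesis genes rose in 8 of 24 and fell in 2 (adjusted p = 0.0274 and 0.0249, or adjusted p = 0.796 and 0.727 with an estimated correlation), while fry called neither list and gave both the opposite direction. In all 6925 genes changed, 2932 up and 3993 down, or 3443 up and 3554 down with DESeq2. The count was 1632 without 3-day overload replicate 1, which held most of the UMIs. Of the 16 genes that the rule named here, 10 were also called without that replicate, those named above among them.

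After 7 days of overload 4116 genes rose and 5616 fell, 9732 in all. Myh3 rose by 5.99 (12.7 ± 2.12 CPM, n = 4, against 0.11 to 0.305), Myh8, the neonatal myosin, by 5.33 and Runx1 by 5.30 (299 ± 25.6 CPM). Postn (ENSMUSG00000027750), periostin of the matrix, was at 140 ± 109 CPM against 1.16 to 1.95 (5.97, SE 0.76). Slc24a2, a sodium and calcium exchanger, rose by 5.07. Prr33 fell from 2037 to 2172 CPM to 104 ± 19.2 (-4.34), and transcripts of globin fell (Hbb-bs -4.26, Hba-a2 -4.09). Whether the globin transcripts came from the myonuclei themselves was not tested. Matrix genes rose in 25 of 27 with 0 falling (Cthrc1 7.32, Adam12 3.63, Col3a1 1.93; adjusted p = 2.91e-10, or adjusted p = 0.468 with an estimated correlation). Of these, Col1a1 (2.31) was not called without basal replicate 1 (2.02, adjusted p = 0.0715). Denervation response genes rose in 13 of 18 and fell in 3 (Kcnn3 3.57, Myog 2.60; adjusted p = 4.36e-04), synaptic genes rose in 8 of 16, 9 adjusted over the list alone, and fell in 4 (Ncam1 4.45, Chrna1 1.66; adjusted p = 0.0225), and mechanical stress genes rose in 7 of 21 and fell in 3 (Ankrd1 4.59; adjusted p = 0.00788). These adjusted p were 0.684, 0.761 and 0.824 with an estimated correlation.

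Fast contractile genes fell in 10 of 13 (Tnnc2 -2.03), glycolysis genes in 11 of 17 (Eno3 -1.08, Gapdh -2.32), respiratory genes in 22 of 25 (Cox6a2 -2.82) and fatty acid genes in 14 of 15 (Cpt1b -3.79), with 0 rising in each. Their adjusted p were 2.4e-04, 0.0225, 1.28e-04 and 4.94e-06, and with an estimated correlation 0.684, 0.824, 0.727 and 0.721. Proliferation genes rose in 14 of 18 and fell in 2 (Top2a 3.80; adjusted p = 0.00224), and Schwann repair genes rose in 5 of 12, 7 adjusted over the list alone, and fell in 3 (adjusted p = 0.0342). The adjusted p with an estimated correlation were 0.78 and 0.796. Recruited macrophage genes rose in 7 of 12 and fell in 1, and immune and fibroblast markers each rose in 5 of 10 and fell in 2, none of the 3 lists being called by camera. The immune markers stood at 2.01% and 2.16% of their level in macrophages in the Exp1 suspensions and at 0.927% and 0.702% in Exp2, against 0.702% and 0.527% in basal. Ribosome biogenesis genes rose in 1 of 24 and fell in 9 (0 and 8 adjusted over the list alone; Fbl -1.37), and proteasome genes rose in 5 of 31 and fell in 13 (Psmb6 -1.06), neither list being called. Each experiment alone held a single basal suspension, so neither replicates these calls.

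**Figure D2:**
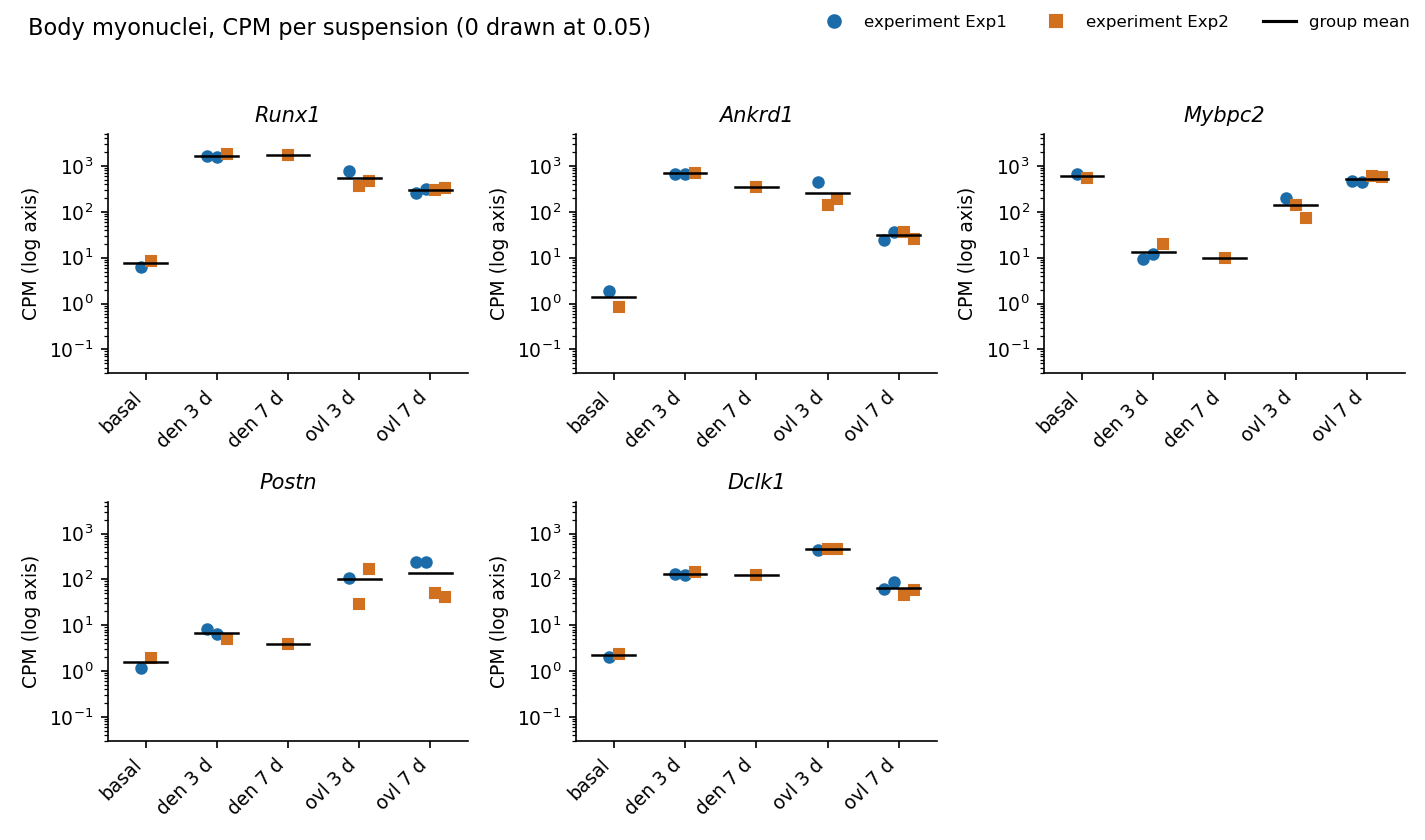
CPM (log axis, 0 drawn at 0.05) of 5 genes in body myonuclei of each suspension, by condition; circles are Exp1, squares Exp2 and the line is the mean of the group. Runx1 stands at 6.41 to 8.66 in basal and at 1683 on average after 3 days of denervation, and Postn at 140 on average after 7 days of overload.

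**Figure D3:**
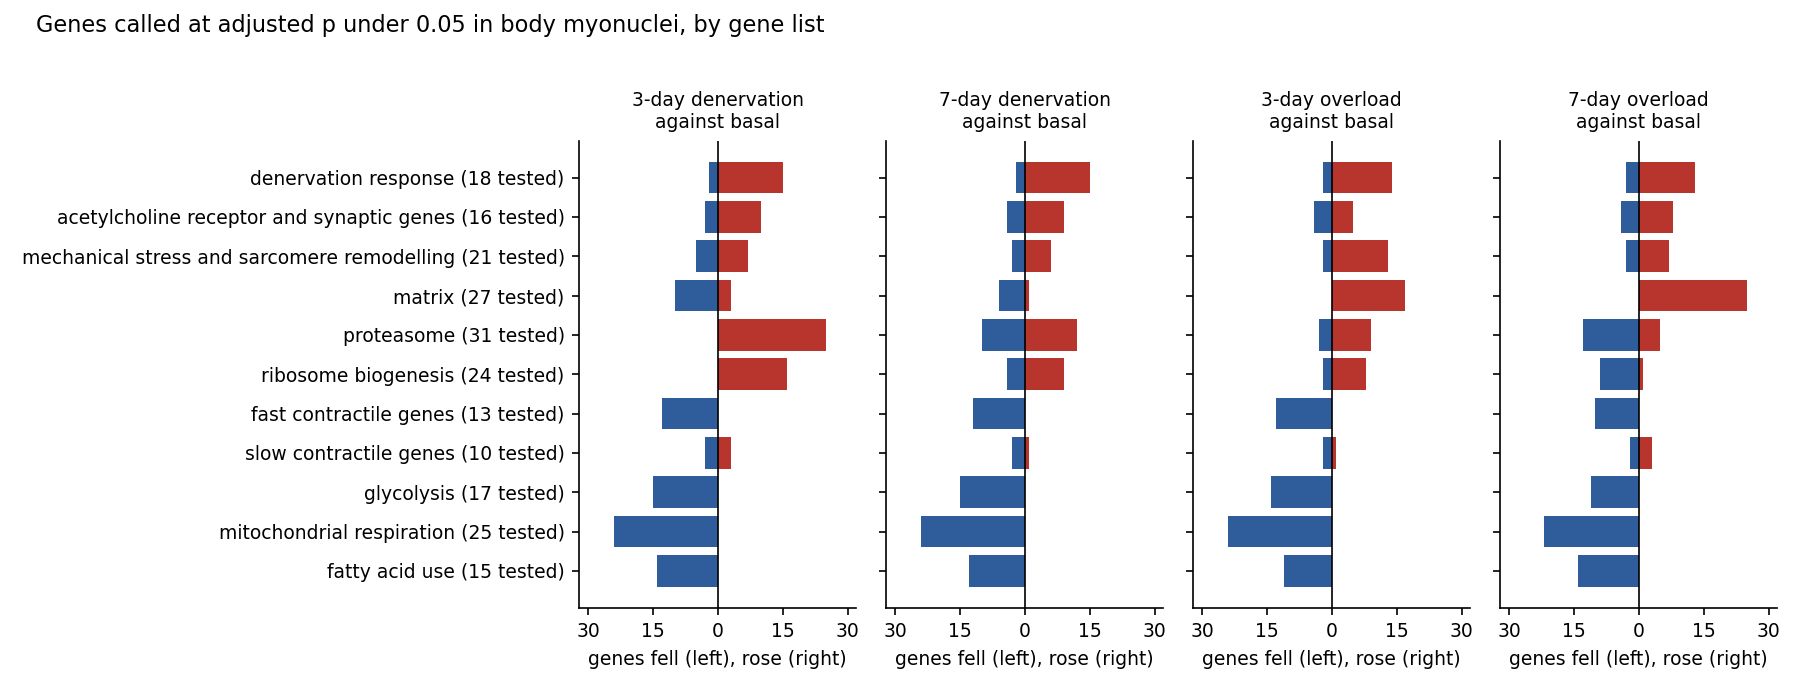
Number of genes that rose (to the right) and fell (to the left) in body myonuclei for 11 gene lists and the 4 comparisons with basal. Matrix genes rose in 25 of 27 after 7 days of overload, while the proteasome list, with 12 up and 10 down after 7 days of denervation, has 7 up and 14 down with DESeq2.

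Denervation and overload were also compared directly, which asks where the responses to atrophy and to growth part. At 3 days 5361 genes differed, 2967 higher and 2394 lower with denervation, a balance that turns with DESeq2 (2467 higher and 3217 lower). Matrix genes were lower in 21 of 27, 24 adjusted over the list alone (Cthrc1 -4.86; adjusted p = 6.58e-19), as were 12 of 21 genes of mechanical stress with 3 higher (13 and 4 adjusted over the list alone; Lmcd1 -4.18; adjusted p = 3.47e-06) and 10 of 15 immediate early genes with 1 higher (Fos -3.65; adjusted p = 2.14e-04). The adjusted p were 0.387, 0.725 and 0.468 with an estimated correlation. Markers of other cells were lower too: immune markers in 9 of 10, recruited macrophage genes in 11 of 12 (12 adjusted over the list alone) and fibroblast markers in 5 of 10 (6 adjusted over the list alone), with 0 higher. Their adjusted p were 0.00809, 7.6e-04 and 0.019, and with an estimated correlation 0.796, 0.727 and 0.796. Kcnn3 was higher with denervation by 4.31 and Gadd45a by 3.03, and Glis3 was lower by a log2 fold change of -6.00. Without 3-day overload replicate 1 the count was 1216, and then Cthrc1 (-5.35, adjusted p = 0.246) and Fos (-1.59, adjusted p = 0.735) were not called. Exp2 alone held a single suspension of 3-day denervation, and Exp1 alone a single one of 3-day overload.

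At 7 days 5192 genes differed, 2525 higher and 2667 lower with denervation, or 1595 and 2706 with DESeq2. Enpp3 was higher by 6.73 and Ankrd55 by 6.40, while Mybpc2 (-5.88) and Meg3, a long noncoding RNA (-5.87), were lower. Denervation response genes were higher in 13 of 18 and lower in 1 (2 adjusted over the list alone; Gadd45a 5.53, Kcnn3 3.53; adjusted p = 2.13e-09). Lower with denervation were 10 of 13 fast contractile genes (Myh4 -2.24, Myh1 -2.29), 14 of 17 glycolysis genes (Eno3 -3.57), 21 of 25 respiratory genes (Cox7a1 -2.82) and 20 of 27 matrix genes (Col1a1 -4.36), with 0 higher. Adjusted over the list alone these were 12, 15, 21 and 24. Their adjusted p were 1.29e-13, 3.63e-12, 4.76e-06 and 4.01e-16. With an estimated correlation the adjusted p of the 5 lists were 0.418, 0.387, 0.418, 0.713 and 0.387. Fibroblast markers were lower in 9 of 10 in the same comparison (adjusted p = 8.3e-04, or adjusted p = 0.727 with an estimated correlation). Numbered suspensions summed to 1 replicate gave 3246 genes, Exp2 alone 7660, and Exp1 holds no 7-day denervation.

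The myosin heavy chain transcripts of body myonuclei shifted in both conditions. In basal nuclei 50.0% ± 2.24 (n = 2) of the myosin UMIs were Myh4, 28.0% ± 1.31 Myh1 and 21.8% ± 3.34 Myh2, the fast myosins from the fastest to the slowest. After 3 days of denervation Myh4 was 28.5% ± 3.14 (n = 3) and embryonic Myh3 4.15% ± 0.74, against 0.00317% in basal. In the 7-day denervation suspension Myh2 was 46.8% and Myh4 23.7%. After 7 days of overload Myh1 was 43.9% ± 1.57 (n = 4) and Myh4 36.1% ± 4.74. At 3 days of overload Myh1 was 66.2% ± 7.62, from 40 and 177 myosin UMIs in 2 of its 3 suspensions, and 75.6% in nuclei of at least 1000 UMIs. These shares were not tested. The highest Myh4 share of any suspension was 32.1% at 3 days of denervation and 40.1% at 7 days of overload, and the lower basal one was 48.4%.

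Nuclei under the nerve terminal express synaptic genes at high levels in basal muscle, and some of these fell there with denervation. The class held few nuclei: 10 and 74 in the basal suspensions and 13 to 38 in the 4 denervated ones. In junction myonuclei Chrne fell from 737 to 936 CPM to 146 ± 45.9 (n = 4, log2 fold change -2.76), Colq, the collagen tail of acetylcholinesterase, from 574 to 605 to 108 ± 37.9 (-2.49) and Ache from 271 to 425 to 58.3 ± 23.3 (-2.80). Ncam1 (ENSMUSG00000039542) rose from 681 to 1495 to 5056 ± 672 (2.18). Spp1, osteopontin, had 0 counts in basal junction myonuclei and was at least 55.0-fold higher. Tafa4 fell by 6.91 on the log2 scale. Of 13 synaptic genes tested 3 rose, 5 adjusted over the list alone, and 6 fell (adjusted p = 0.386). Against body myonuclei of the same suspensions, the effect of denervation differed for 230 of 16208 genes by a test of the difference (edgeR, 8 suspensions), 189 of them with the lower effect in junction myonuclei. Denervation changed 835 of 4153 genes (373 up, 462 down) and overload 102 (55 up, 47 down), from 2 suspensions of overload at 7 days. Leaving out 1 suspension gave 167 genes for denervation without basal replicate 2 and 543 without 7-day denervation replicate 1, and 14 for overload without basal replicate 2. DESeq2 called 308 and 31. The synaptic list with overload had 1 of 13 rising and 0 falling, with an adjusted p of 0.665.

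**Figure D4:**
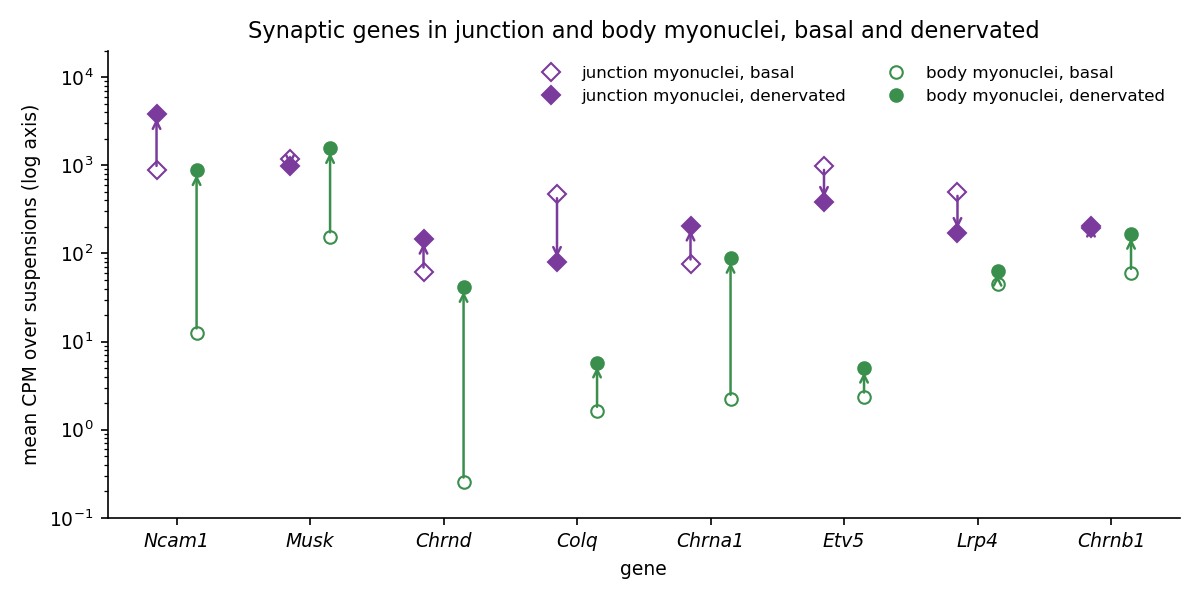
Mean CPM (log axis) of 8 synaptic genes in junction and body myonuclei, each as a line from basal to denervated, with both kinds of nuclei scaled together, so that values differ from those of junction myonuclei scaled alone. Ncam1 went from 885 to 3791 in junction and from 12.7 to 876 in body myonuclei, and Colq from 473 to 81.0 and from 1.63 to 5.74.

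Schwann cells, which wrap the axons, lost myelin transcripts after denervation and gained those of the repair state. Pmp22, a membrane protein of myelin, fell from 1584 to 2299 CPM to 20.8 ± 16.2 (n = 4, log2 fold change -7.17, SE 0.52), and Prx fell by 6.33. Gdnf, a growth factor for motor neurons, had 0 basal counts and was at least 28.0-fold higher, the neurotrophin receptor Ngfr at least 14.9-fold and Atf3 at least 47.1-fold. Runx2 rose by 7.88 and Tnc by 4.82. Of 13 myelin genes 11 fell and 0 rose (adjusted p = 5.26e-10), and of 12 repair genes 8 rose, 9 adjusted over the list alone, and 1 fell (adjusted p = 7.44e-09). The adjusted p were 0.18 and 0.176 with an estimated correlation. Denervation changed 645 of 4085 genes, 252 up and 393 down, or 100 up and 104 down with DESeq2. DESeq2 called 204, with 6 myelin genes falling, and edgeR without basal replicate 2 called 421. Overload, represented by 1 suspension of 7 days, gave 4 genes by edgeR (3 up, 1 down), with 397 at an unadjusted p under 0.05 and 6 by DESeq2. That count was 0 without 7-day denervation replicate 1, 21, 61 and 87 without 3-day denervation replicates 1, 2 and 3, and 83 and 31 without basal replicates 1 and 2. No member of the repair and myelin lists was called with overload, though 3 myelin genes fell when adjusted over the list alone (adjusted p = 3.81e-05, or adjusted p = 0.215 with an estimated correlation).

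Macrophages changed in genes of proliferation and of the resident and recruited states. With denervation 9 of 18 proliferation genes rose, 15 adjusted over the list alone, with 0 falling (adjusted p = 9.84e-12, or adjusted p = 0.0979 with an estimated correlation). Kif14, a mitotic kinesin, had 0 basal counts and was at least 14.8-fold higher. Kif11 (3.07) and Cenpf (3.25) were not called without basal replicate 2 (2.73, adjusted p = 0.0525, and 2.48, adjusted p = 0.0578). Resident macrophage genes fell in 3 of 9 (6 adjusted over the list alone) and recruited ones rose in 2 of 11. With overload Timd4 (ENSMUSG00000055546), a receptor of resident macrophages, fell from 198 to 226 CPM to 14.2 ± 10.1 (n = 7, -3.61), Lyve1 by 3.42, Retnla by 5.82 and Ccl24 by 5.76. Timp1 was at least 12.1-fold higher. All 9 resident genes fell (adjusted p = 4.85e-06), and 7 of 11 recruited genes rose, 9 adjusted over the list alone (Lgals3 1.99; adjusted p = 6.45e-08), with 2 of 18 proliferation genes. With an estimated correlation the adjusted p were 0.184 and 0.0979. The difference between the conditions was not tested. Denervation changed 1384 of 11767 genes (583 up, 801 down; 298 and 672 with DESeq2) and overload 2925 (1227 up, 1698 down; 700 and 1707 with DESeq2). Without basal replicate 2 the counts were 696 and 1781, without basal replicate 1 overload gave 1919, and without 7-day denervation replicate 1 denervation gave 920.

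Fibro-adipogenic progenitors changed most genes among the classes outside the fibre, 3408 of 14683 with denervation (1717 up, 1691 down; 1037 and 1734 with DESeq2) and 6919 with overload (3233 up, 3686 down; 2401 and 3978 with DESeq2). With overload Cthrc1 (ENSMUSG00000054196), a secreted protein of activated fibroblasts, reached 199 ± 60.3 CPM (n = 7) against 1.49 to 1.86 (6.91, SE 0.63), Postn 2296 ± 930 against 10.6 to 41.7 (6.57, SE 0.65) and Chl1, a cell adhesion protein, 544 ± 203 (8.71). Tnc rose by 5.91, and Inmt fell by 8.53. Matrix genes rose in 19 of 27 and fell in 5 (adjusted p = 3.93e-09), and proliferation genes rose in 17 of 18 (Mki67 3.23; adjusted p = 2.35e-09). With an estimated correlation the adjusted p were 0.215 and 0.18. With denervation Chl1 rose by 7.57, Postn by 4.15 and Timp1 by 3.89, matrix genes rose in 14 of 27, 16 adjusted over the list alone, and fell in 4 (adjusted p = 4.85e-06, or adjusted p = 0.281 with an estimated correlation), and proliferation genes in 3 of 18. Mybpc2, a myofibre gene, fell here by 6.54, and 153 of the 322 genes at least 10 times higher in body myonuclei were called, 47.5% against 22.7% of other genes. Without basal replicate 1 the counts were 1661 and 3881, and denervation gave 2105 without basal replicate 2 and 1979 without 7-day denervation replicate 1. Without the 2 clusters of mostly overload nuclei overload gave 3796.

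In muscle stem cells overload lowered genes of quiescence and raised genes of the cell cycle. Chodl fell from 824 to 889 CPM to 153 ± 158 (n = 7, -4.12), Calcr, the calcitonin receptor that holds these cells at rest, by 3.60 and Pax7 by 1.21. Hmga2, a chromatin protein of growing progenitors, had 0 basal counts and was at least 38.9-fold higher. Quiescence genes fell in 10 of 12 (adjusted p = 8.85e-06), and proliferation genes rose in 13 of 17, 16 adjusted over the list alone (Tpx2 2.95; adjusted p = 1.72e-08). With an estimated correlation the adjusted p were 0.223 and 0.18. Of 10 activation genes 4 rose, 5 adjusted over the list alone, and 1 fell (adjusted p = 0.03, or adjusted p = 0.29 with an estimated correlation). With denervation 3 of 12 quiescence genes fell, 4 adjusted over the list alone, and 1 of 10 activation genes rose. Of 17 proliferation genes 0 were called by edgeR, though the list was (adjusted p = 0.0268, or adjusted p = 0.493 with an estimated correlation). Overload changed 2959 of 8907 genes (1327 up, 1632 down, or 795 and 1739 with DESeq2) and denervation 731 (292 up, 439 down). DESeq2 called 394 with denervation. Without basal replicate 1 the counts were 1923 and 419, and denervation gave 351 without basal replicate 2 and 166 without 7-day denervation replicate 1.

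Endothelial nuclei had 1982 of 9909 genes changed with overload (747 up, 1235 down) and 1074 with denervation (374 up, 700 down). With overload Plvap, of fenestrated vessels, rose by 1.47, Aplnr, the apelin receptor, by 1.18, and Kdr, the main receptor for vascular growth factor, fell by 1.32. Of 14 angiogenic genes 4 rose and 3 fell, and 8 of 16 proliferation genes rose (adjusted p = 4.85e-06, or adjusted p = 0.246 with an estimated correlation). Of these Mki67 (3.55) was not called without 3-day overload replicate 3 (2.87, adjusted p = 0.0536). With denervation 2 angiogenic genes fell and 0 proliferation genes were called by edgeR. Several of the largest falls with denervation were of myofibre genes, such as Mybpc2 (-6.66) and Prr33 (-7.09). DESeq2 called 644 genes with denervation. Leaving out basal replicate 1, basal replicate 2 or 7-day denervation replicate 1 gave 380, 527 and 426 genes for denervation. For overload it was 975 and 1309 without basal replicates 1 and 2, and 1259 without 3-day overload replicate 3.

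Mural nuclei, of pericytes and smooth muscle, had 822 of 6267 genes changed with overload, at 7 days only (299 up, 523 down) and 519 with denervation (126 up, 393 down), and tenocytes 352 of 6735 (147 up, 205 down) and 227 (44 up, 183 down). In tenocytes overload raised 9 of 27 matrix genes, 12 adjusted over the list alone, with 0 falling (Adam12 2.42, Col3a1 1.89, Lox 1.73; adjusted p = 7.55e-09, or adjusted p = 0.0979 with an estimated correlation), and also Spp1 (4.83), Cthrc1 (4.68) and Bcl3 (4.38). Aoah, a gene of immune cells, rose there as well (4.22), but was not called without basal replicate 1 (3.035) or 2 (5.17). Nor was it without 3-day denervation replicate 2 (4.22, adjusted p = 0.0568) or 3 (4.22, 0.0518), or without 7-day overload replicate 3 (4.20, 0.0651). Other immune genes, looked up after the results were seen and not run under the alternatives, rose too: Ptprc (3.30, adjusted p = 0.00295), Ly86 (3.53, 0.0393) and Marchf1 (3.45, 0.0338). These tenocyte effects of overload rest at 3 days on replicate 1 alone, with 24 nuclei. With denervation 1 of 27 matrix genes rose, or 2 with 1 falling adjusted over the list alone. In mural nuclei overload raised 3 of 5 proliferation genes, 5 adjusted over the list alone (adjusted p = 2.79e-05, or adjusted p = 0.215 with an estimated correlation), and denervation 0 of 5 by edgeR. Of the 3, Mki67 (4.52) was not called without basal replicate 1 (4.71) or 2 (4.37), or without the experiment term (4.57, adjusted p = 0.0744). Nor was it without 7-day overload replicate 2 (4.70, adjusted p = 0.0994), 3 (4.595, 0.0635) or 4 (4.50, 0.0843), or without 3-day denervation replicate 2 (4.53, 0.0536). Top2a (5.15) was not called without basal replicate 1 (0.16) or 7-day overload replicate 1 (0.0582). Adgre1, a macrophage gene with 0 basal counts, was at 56.6 ± 23.0 CPM (n = 4) in them with overload. Without basal replicate 2 the mural counts were 241 and 99 and the tenocyte counts 215 and 31. Mural denervation gave 165 without 7-day denervation replicate 1, and tenocyte overload gave 205 without basal replicate 1 and 1212 without 3-day overload replicate 1. DESeq2 called 282 and 178 mural and 183 and 78 tenocyte genes, and of the 183 with overload 100 rose and 83 fell, so that balance turns.

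The Visium sections asked how the whole tissue changed at 7 days. With denervation Aqp4 fell from 24.9 ± 1.10 CPM (n = 2) in sham to 0.782 ± 0.262 (log2 fold change -4.99, SE 0.23), and Mybpc2 fell by 3.83. Chrng rose from 0.185 to 191 ± 7.31 (9.96, SE 0.26), and Ankrd1 by 8.49. S100a8, a neutrophil protein, reached 370 ± 82.5 CPM from 1 sham count (ratio 8160, interval 1460 to 322000). Of 13663 genes 8265 changed, 4581 up and 3684 down. Denervation response genes rose in 16 of 18 (Gadd45a 6.43, Myog 6.25), Schwann repair genes in 12 of 16 (Ngfr 4.49, Runx2 3.32), immune markers in 10 of 10 (Cd68 3.25), proteasome genes in 22 of 31 and ribosome biogenesis genes in 18 of 24 (19 adjusted over the list alone). Falls were counted in 13 of 16 myelin genes with 3 rising (Prx -4.81), 16 of 16 glycolysis genes (Eno3 -2.67), 24 of 25 respiratory genes (Idh2 -2.90), 11 of 13 fast contractile genes (Myh4 -3.54) and 9 of 10 endothelial markers. The adjusted p of the denervation response list was 3.81e-07. The lowest adjusted p that any Visium list had with an estimated correlation was 0.317.

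With overload Cthrc1 rose from 0.175 to 162 ± 39.3 CPM (9.72, SE 0.35), Postn by 6.76, Myh3 by 7.18 and Mymk, which drives myoblast fusion, by 7.05. Amd1, an enzyme of polyamine synthesis, fell from 177 ± 1.89 to 22.2 ± 3.37 CPM (-2.99), Wnt4 by 2.81 and Mstn by 2.33 on the log2 scale. Matrix genes rose in 26 of 27 (Col1a1 4.11; adjusted p = 3.92e-14, or an adjusted p of at least 0.317 with an estimated correlation), proliferation genes in 17 of 17 (Mki67 4.06), recruited macrophage genes in 12 of 12 (Trem2 4.58), slow contractile genes in 8 of 10 with 1 falling (Myh7 3.76), angiogenic genes in 10 of 16 with 2 falling (Apln 2.57) and mechanical stress genes in 16 of 21 with 2 falling. Respiratory genes fell in 25 of 25 (Cox7a1 -1.20), fatty acid genes in 15 of 15 (Lpl -2.19), glycolysis genes in 16 of 16 and proteasome genes in 13 of 31. In all 8213 genes changed, 4339 up and 3874 down, or 3109 and 3183 with DESeq2. The overload sections were all in the second Visium experiment and the sham sections in the first, so experiment and overload cannot be told apart. Among 13123 genes measured in both assays, 75.5% of the 6758 called in body myonuclei at 7 days of denervation had the same sign in the sections, against 56.8% of those not called. For overload it was 71.5% of 6809 against 55.1%.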

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

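Of the tests reported in this part, the splits of the overload suspensions by day were chosen only after the result was seen. In body myonuclei the days themselves differed. Between 7 and 3 days of denervation 5472 genes differed by an edgeR test of that difference, 2249 higher and 3223 lower at 7 days, and between 7 and 3 days of overload 2918 did, 1519 higher and 1399 lower. The first difference rests on the single suspension of 7-day denervation. For overload the 35 splits of the 7 suspensions into 3 and 4 were run: the real one gave 2918 genes and the highest of the others 134. Experiments differ, however, and only 18 of the splits keep the number of Exp2 suspensions in each group (highest other 92). These are too few for a share under 0.05, so the splits do not exclude chance. The 3-day suspensions are also much shallower, and this was not separated from the day. Between 3-day denervation and 3-day overload the real split gave 5361 genes and the highest other 4, in 1 of 10 splits, which are too few for a share under 0.05.

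Of 16 synaptic genes, 8 responded to denervation in opposite or unequal ways in junction and body myonuclei, by an edgeR test of the difference between the effects. The other 8 were not called, among them Chrne (difference -0.02) and Ache (-0.23), which fell in both. The effect in junction myonuclei minus that in body myonuclei was -3.92 log2 for Ncam1, -3.64 for Musk, -6.10 for Chrnd, -3.92 for Colq, -4.03 for Chrna1, -2.38 for Etv5, a transcription factor of synaptic nuclei, -1.99 for Lrp4, the agrin receptor, and -1.47 for Chrnb1. With both kinds of nuclei scaled together, Etv5 went from 990.0 to 388.6 CPM in junction myonuclei and from 2.37 to 5.01 in body myonuclei, and Musk from 1171 to 993.1 and from 155.8 to 1558. A technical explanation is that body myonuclei were counted among junction myonuclei once denervated body nuclei express receptor genes. Genes at least 4 times higher in basal junction than body myonuclei would then fall alike. Of 90 such genes called, 72 fell and 18, or 20%, rose (exact 95% interval 12.3% to 29.8%). The genes were picked by their level in the same basal suspensions that the test compares with, which favours falls. The interval also takes the calls as independent. For this explanation at most 5% were predicted to rise, and the interval lies above that. The limit set against it was 20%, which the interval spans. The explanation and a real loss of synaptic transcription therefore cannot be told apart for these genes. Ncam1 stood higher in denervated junction myonuclei (3791 CPM) than in basal junction (885) or denervated body myonuclei (876). A mixture of those 2 at their mean levels would not give that level. Scaled alone, the lowest denervated junction suspension (4147) was above the highest basal one (1495). Body myonuclei counted there need not hold the mean level, since the class was named by genes that themselves change with denervation. The means of Chrna1 and Chrnd were also higher, but in junction myonuclei the rise of Chrnd (1.30) was not called (adjusted p = 0.0509). That of Chrna1 (1.42) was not called without basal replicate 1 (1.155) or without basal replicate 2 (2.09). Nor was it without 7-day denervation replicate 1 (1.29, adjusted p = 0.0834), with DESeq2 (1.48, 0.321) or with no filter (1.48, 0.0569). For the genes that fell the mixture stays open, and for Ncam1 it is not excluded.

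Myofibre genes were called in nuclei of other classes after denervation, in 58.3% of those tested in endothelial nuclei against 10.1% of other genes there, 47.5% against 22.7% in fibro-adipogenic progenitors and 22.9% against 3.23% in tenocytes. In muscle stem cells it was 18.3% against 8.13% and in macrophages 17.8% against 11.7%. Schwann cells went the other way, 9.09% (1 of 11 genes, of the opposite sign to body myonuclei) against 15.8%, and in mural nuclei 3 such genes were tested. Free RNA from myofibres predicts that they carry the sign they have in body myonuclei. Of 271 such calls over 7 classes 260, or 95.94%, did, above the 90% set for that explanation, against 83.9% of the other called genes. With overload 217 of 235 did, or 92.3%, against 82.1%, but there myofibre genes were called more often than others only in endothelial nuclei (46.5% against 19.6%) and in Schwann cells (1 of 11 genes). Doublets with myonuclei predict that few nuclei hold most of these transcripts. The top 5% of nuclei held a median of 49.0% of them (11.4% to 89.0%), between the limits of 25% and 50% set for that test, so doublets stay open. Free RNA may therefore account for the direction of many falls of myofibre genes outside the fibre after denervation. A change within those cells was not tested apart from it. In classes with more than 1 such call, the median log2 change over that in body myonuclei ran from 1.12 (progenitors) to 3.66 (tenocytes). Free RNA at a steady level would not exceed the change in its source. Doublets predict the same sign as well, so the signs do not separate them from free RNA. Leaving the myofibre genes out gave 3298 genes in fibro-adipogenic progenitors and 1026 in endothelial nuclei. That does not show the remaining calls to be free of myofibre RNA, since the limit of 10 times passes over genes such as Mybpc2. In basal endothelial nuclei Mybpc2 stood at 169.6 and 97.9 CPM. In body myonuclei it was 294.2 on average over all suspensions, and 686.7 and 551.3 in the basal ones.

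Matrix genes rose in body myonuclei after 7 days of overload, when fibro-adipogenic progenitors were 26.1% of nuclei. Free RNA from these cells was set from fibroblast markers outside the matrix list. In the 4 suspensions it would give 109%, 116%, 162% and 130% of the summed rise of the called matrix genes, at free levels of 13.1%, 12.9%, 4.61% and 3.18% of the level in the progenitors. A part cannot exceed the whole, so where the free level was above that in body myonuclei the markers set it too high. In basal this held for Fbn1 (103.2 against 24.41 CPM), but not for Col1a1 (20 against 55.32). Free RNA may give part or all of the summed rise, but these percentages do not measure how much. The called matrix genes differed. The free level reached the level in body myonuclei for Postn (269.4 against 140.4 CPM) and about did for Cthrc1 (20.4 against 20.5). It fell short for Col1a1 (166.8 against 329.1), Timp1 (2.95 against 10.7), Serpinh1 (18.0 against 41.6) and Col6a1 (14.2 against 22.2). It also did for Lox (7.999 against 13.4), Bgn (27.73 against 45), Sparc (48.51 against 77) and Col1a2 (257 against 293.6). For Adamts5 it went from 36.38 in basal to 20.99, while the level in body myonuclei went from 24.89 to 43.14. Loxl1 and Mmp14 were nearly level. For every other called matrix gene, such as Col3a1 and Fn1, the free level was above that in body myonuclei. Matrix transcription by the myonuclei themselves stays open, above all where the free level fell short. The markers can also change within the progenitors. For the 3-day rise the same test was not run.

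3 of 34 groups tested held a sample far from the others, where about 1 in 20, or 1.7, is expected by chance. Of these 3, 2 rest on the same library of 3-day overload. There 4 libraries of 3 suspensions were counted as separate samples. The share of Schwann cells was 0.36% in 7-day overload replicate 2 and 0.259% to 0.262% in the other 3. Library 1 of 3-day overload had a median of 1659 UMIs per nucleus against 769 to 814 in the others, and a total of 5355073 against 181373 to 542686. It is the only one of them from Exp1, so experiment and depth cannot be told apart there. Its body myonuclei numbered 786, against 24 and 90 in the other 2 suspensions.

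The tag libraries of the sorted cells hold a signal that no comparison here uses. Of the cells kept, 33.83% and 34.43% could be given a tag in the 2 lanes of batch A, and 14.71% to 16.82% in the 3 lanes of batch A2. The tags could not be paired with conditions, so nothing further was tested on them.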

How the results depend on the processing

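Of the tests reported in this part, those added only after the results were seen are junction myonuclei counted with body myonuclei, the chip 1 basal library left out, the 2 shallow 3-day overload suspensions left out, genes 10 times higher in body myonuclei left out, and the progenitors without 2 overload clusters. Of 530 values that 63 counts and shares took under the alternatives, 448 stayed within 1.5 times the reported count or within 1 SD, and 82 did not. For named genes in body myonuclei 4624 of 4691 values kept direction and call, as did 2607 of 2738 in other classes, 711 of 715 in Visium and 272 of 319 for class shares. No named gene or share was reversed in any setting. The rule takes called genes with large changes, for comparisons with basal on the fitted side in every treated suspension. Reversals of such genes were therefore unlikely from the start. A gene counts once for each comparison in which it is named. In body myonuclei 25 such calls were lost without 3-day overload replicate 1 and 23 in Exp2 alone. In other classes 29 were without basal replicate 2, 28 without basal replicate 1 and 18 with no experiment term. Of the 19 shares 9 lost theirs without basal replicate 2, 8 with TMM-style factors and 7 without the 2 shallow suspensions.

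With libraries as replicates and experiment and chip as the replicate block, body myonuclei gave 8798, 9798, 6994 and 9529 genes for 3- and 7-day denervation and 3- and 7-day overload. With that block 3 class shares changed at 3 days of denervation, against 0 by edgeR on suspensions (3 at an unadjusted p under 0.05). Where a reason is not given below, the cause was not tested.

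Exp2 alone gave 1784 genes for 3-day overload and 1278 between 3-day denervation and 3-day overload, with fewer suspensions, and these shallow. Summing numbered suspensions left 3246 genes between 7-day denervation and 7-day overload. DESeq2 gave fewer genes in small classes: with denervation 644 endothelial, 178 mural, 394 muscle stem cell, 308 junction, 204 Schwann and 78 tenocyte, and with overload 282 mural, 31 junction and 183 tenocyte. With no filter on low counts mural nuclei gave 795 and 1293 genes for denervation and overload, tenocytes 444 and 540, and with overload junction myonuclei gave 57 and Schwann cells 24. With no experiment term tenocytes gave 48 genes with denervation and Schwann cells 0 with overload by edgeR; with that term edgeR had 397 at an unadjusted p under 0.05 and DESeq2 called 6. Without the 2 shallow suspensions endothelial overload gave 1259, and the class shares changed were 5 at 3 days of overload and 2 at 3 days of denervation. Without the 2 clusters of mostly overload nuclei, progenitors gave 3796. For class shares no experiment term and TMM-style factors both gave 0 classes by edgeR at 7 days of denervation, and TMM-style factors 2 at 7 days of overload.

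Camera with an estimated correlation called 0 lists in body myonuclei, 0 in other classes and 0 in Visium, against 62, 19 and 35 at the preset correlation and 19, 14 and 46 with fry. The estimated correlation allows for genes of a list moving together, so the list tests depend on this choice and the counts of genes do not. The share of Myh1 at 3 days of overload was 75.6% in nuclei of at least 1000 UMIs. Among genes called at an adjusted p under 0.01, 79.0% and 74.0% had the same sign in Visium for denervation and overload.

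Leaving out 1 suspension at a time gave ranges of 6904 to 9072 genes in body myonuclei for 3-day denervation, 7621 to 9943 for 7-day denervation, 1632 to 6991 for 3-day overload, 6944 to 9976 for 7-day overload, 1216 to 5910 between the conditions at 3 days and 4142 to 5912 at 7 days. The lowest 3-day values, 1632 and 1216, are without 3-day overload replicate 1. For denervation and overload the ranges were 1661 to 3573 and 3881 to 7096 in progenitors, 380 to 1293 and 975 to 2026 in endothelial nuclei, 166 to 840 and 1923 to 3052 in muscle stem cells, and 696 to 1407 and 1781 to 2947 in macrophages. They were 99 to 637 and 241 to 989 in mural nuclei, 421 to 807 and 0 to 87 in Schwann cells (0 by edgeR without 7-day denervation replicate 1), 31 to 271 and 205 to 1212 in tenocytes, and 167 to 900 and 14 to 130 in junction myonuclei. Visium gave 7031 to 8457 and 6690 to 8501 without 1 section. Class shares changed numbered 0 to 3 and 0 to 5 for 3- and 7-day denervation, and 9 to 11 and 2 to 6 for 3- and 7-day overload. The libraries behind each large move are named with their values in the report.

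On simulated data 11.9% of genes changed 2-fold were found in body myonuclei for 3-day overload, against 61.2% for 3-day denervation, and 2.99% in Schwann cells for denervation. Small changes in these 2 are therefore mostly missed. The tag limit of 60% was not run, since tags had no condition, and Exp1 alone gives no value for 7-day denervation, which it does not hold. Leaving out 7-day denervation replicate 1 leaves no such group to compare.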

Other observations

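The sorted single cells, which enter no comparison, hold states of the muscle stem cells and Schwann cells. They were sorted as CD31-positive endothelial cells together with cells negative for CD31, Sca1 and CD45, a sort meant to leave out connective tissue and immune cells. The 5 lanes kept 4787, 5613, 5606, 5825 and 5900 cells, with a median of 6046 to 9375 UMIs. Without doublet calls 4688, 5554, 5450, 5635 and 5711 were left. Of these, cells resembling muscle stem cells were 46.0% to 65.2% of a lane, differentiating myoblasts 5.72% to 17.4%, endothelial cells 7.28% to 14.5% and Schwann cells 1.64% to 3.25%, and 9.02% to 21.5% stayed unnamed.

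Sizes of clusters include doublet calls. Most clusters resembling muscle stem cells had a mean log2 fold of their markers below the limit of 2 used for nuclei. Schwann cells formed 2 clusters, 217 cells led by myelin genes such as Mbp and 565 led by Apod and Cdh19. Among myoblasts, 1542 cells were led by Myog and by Mymk and Mymx, which drive fusion, and 883 by Acta1, the skeletal actin, and Myh3. A cluster of 1494 cells resembling muscle stem cells was led by histone genes such as H1f5 and H2ac8. Its muscle stem cell markers had a mean log2 fold of only 0.47. A cluster of 646 cells resembling fibro-adipogenic progenitors was led by Mfap5, Aspn and Cthrc1 and held Postn and Cxcl5 among its leading genes. Smaller clusters were mural (461 cells, Rgs5 and Myh11), tenocyte (379 cells, Prg4 and Tnmd) and lymphatic endothelial (169 cells, Ccl21a and Lyve1). An unnamed cluster of 1983 cells was led by Cd74, Lyz2 and C1qa, genes of macrophages.

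Tags differed in the classes of the cells that carried them. Of the cells of batch A2 with the tag CMO304, 26.2% resembled differentiating myoblasts, and of those with CMO305, 49.1% were endothelial and 12.3% mural. Of those with CMO302, 13.6% were Schwann cells. These shares were not tested.

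The Moran's I values deposited for Visium give the spatial pattern of some genes named in the report. With overload Cthrc1 had 0.482 and 0.423 and Postn 0.546 and 0.466, so their spots lay together in the section.

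In nuclei, 1 macrophage cluster led by Neil3 and Top2a came in 81.6% of its nuclei from denervated muscle, and 1 muscle stem cell cluster with Top2a in 92.3% from overloaded muscle. Clusters of progenitors led by Postn and by Diaph3 came in 97.7% and 91.1% from overload. These shares were seen after clustering and were not tested.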
